A study of Mus musculus with 167 samples.

How the data were processed

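Gene expression was measured by RNA-seq in 167 tumours of 119 mice, 115 tumours above and 52 below median survival. Per the labels' protocols, whole tumours were homogenised, total RNA was extracted with a column kit, and strand-specific mRNA libraries were made from it. Per the submitters' processing notes, the authors used kallisto 0.46.1, which assigns reads to transcripts without full alignment, and the build GRCm38, and they also name DESeq2 and DESeq. The settings of these tools and the annotation release are not given in the sources used here. The deposited table holds an estimated count for each of 36118 genes in each tumour, given as whole numbers, with no normalization. A second deposited table, described by the authors as normalized, holds 22049 of these genes. All 3682183 of its cells equal those of the first table (100%, exact equality), and its genes are those whose counts sum to at least 167, so it was used only for 1 alternative.

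Each column was joined to a tumour by its title. For 165 columns the title named 1 sample, and the 2 columns of mouse GIT-K1 could be joined only to their survival class, strain and mouse. Strain, mouse and tumour number were read from the labels, and a symbol was found for 35825 of the 36118 Ensembl gene IDs. No genome was used here, so positions are not given. All 167 titles carry a library number, 17 of them 145 or above, with 89 distinct numbers of which 67 are used in several titles, and the runs or lanes of the libraries are not given in the sources used here. Of 13861 pairs of libraries, only the 20 of highest correlation were compared with sampling noise, and none of these agreed within it.

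The mouse was the replicate, since survival class is a property of the mouse. Counts of all tumours of a mouse were summed, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F-test, R 4.3.3), after filterByExpr by class. Differences are mice below minus mice above median survival, and a gene passed at a Benjamini-Hochberg adjusted p of 0.05, two-sided. The median biological coefficient of variation was 55.0%. The contrast within strain used the 57 mice of strains with both classes, with strain as a covariate. The interaction used the 37 mice of strains with at least 2 mice in each class, and the strain test the 103 mice of strains with at least 3 mice. These tests, the rule for named genes, the 34 gene lists and most alternatives were fixed before the data were examined.

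Named genes of the survival contrast were the 12 of lowest p in each direction among genes past the threshold with an absolute log2 fold change of at least 0.5 and a mean of at least 5 CPM, leaving out symbols of predicted genes. Of the 24 genes so chosen 1 is not reported here. For the other contrasts the genes of lowest p under the same filters on level and symbol were named, and within strain also under the same limit on fold change. Members of lists named in the text are those that passed over all genes or over the list alone, and for the strain test members among the 4 of lowest p of a list. Log2 CPM were computed with a prior count of 2.

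The gene lists covered mesothelial and mesenchymal markers, cell cycle, matrix and fibroblasts, smooth muscle, endothelium, hypoxia and glycolysis, oxidative phosphorylation, type I and gamma interferon, T cells, B and plasma cells, macrophages, neutrophils, cytokines, complement, p53 and Hippo targets, mesothelioma tumour suppressors, stress response, immediate early genes, cholesterol synthesis, ribosomal proteins, and tissues that a whole tumour of the body cavity can carry along (hepatocytes, pancreatic acinar cells, adipocytes, skeletal muscle, intestine, reproductive tract and gonads, kidney and adrenal, erythroid cells, mast cells, nerve) as well as sex-linked genes. The score of a list is the mean over its members of centred log2 CPM per mouse. Score differences were tested with 100000 permutations of the class labels, two-sided, and adjusted over the 34 lists. Scores between strains were tested by permuting strain labels. Tumours of one mouse were compared by permuting mouse labels within strain, one-sided. The share of counts that a list takes in a library has a Wilson 95% interval, and such intervals and the floor of 3 counts cover counting error only, since reads carry no molecular identifiers here.

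After the data had been seen, 3 checks of libraries were added. The first is the share of counts taken by lists of other tissues, with a limit of 1%. The second is the correlation of each library with the mean of each strain over 300 genes with the highest ratio of variance between to variance within strains. The third is the division of libraries by Svs5 at 10 CPM and by Umod at 2 CPM. The libraries set apart by the second check are those nearer to another strain by over 0.1, and those nearer by less that are also in 1 of the 20 closest pairs over all genes with a library of another strain. Alternatives, with their effect in the closing section, were DESeq2 1.42.0, limma-voom and limma-trend (limma 3.58.1), other scaling, no filter, tumours in place of mice, strain, depth, Y-linked and other-tissue covariates, and subsets of libraries, mice and strains. Figures were drawn with matplotlib 3.10.9.

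The tests were checked on simulated counts with the design of the real data, in which 100 genes differed by 1 and 100 by 2 on the log2 scale. Between classes edgeR recovered 82 and 97 of these genes with 7 false calls among 17044 genes, and limma-voom 80 and 95 with 15 false calls. Within strain edgeR recovered 70 and 88 with 6 false calls among 16809 genes. For the interaction, with the difference placed in the mice below the median of a single strain, edgeR recovered 0 and 2 genes. It made 1 false call among 16740 genes. Between strains edgeR recovered 49 and 80 genes with 21 false calls and limma-voom 52 and 78 with 19, among 17091 genes. A shift of 1 SD was found in 20 of 20 simulated scores, and an unadjusted p under 0.05 in 1 of 20 scores without a shift. The simulated counts hold no single mice with RNA of another tissue, no correlation between genes and, for the class comparisons, no effect of strain. Their false calls therefore do not give the rate in the real counts. There, other splits of the mice gave a median of 533 genes between classes in edgeR, and permuted strain labels 4944. In limma-voom both medians were 0. The shallowest library held 11138491 counts, in which 3 counts make 0.269 CPM. Processing by estimated counts divides reads among similar transcripts, so genes with near-identical copies carry an error that the counts do not show.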

Results

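RNA was sequenced from 167 tumours that arose in 119 mice after asbestos was injected into the peritoneal cavity. Per the labels' protocols, each mouse received 2 doses of 3 mg of crocidolite, a fibrous asbestos that causes mesothelioma, a cancer of the lining of the body cavities. Every mouse was the offspring of a Collaborative Cross male and a MexTAg female. Collaborative Cross strains are inbred mouse lines whose genomes are mosaics of several founder strains, and MexTAg mice carry the SV40 large T antigen under the mesothelin promoter, which directs this oncogene to mesothelial cells. The 35 crosses are called strains here and carry the name of the male's line. The labels place each mouse above or below median survival, and the mice over which that median was taken are not given in the sources used here. There were 83 mice above and 36 mice below. A single tumour was sampled from 84 mice and several, up to 6, from 35 mice. A tumour library held between 11138491 and 35399287 estimated counts, with a median of 22539831, and the sum over the tumours of a mouse reached 143106098.

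The survival classes were unevenly spread over the strains. All 7 LOX mice and all 4 Boon and 4 Rogan mice were above the median, and all 6 TAS mice and all 3 CIS mice were below it. Of the 35 strains, 16 held mice above the median only, 6 held mice below it only, and 13 held both. The chi-square of strain by class over the 119 mice was 58.03 with 34 degrees of freedom (permutation test, p = 0.00088). The number of tumours sampled was 1.39 ± 0.746 (SD, n = 83) per mouse above and 1.44 ± 0.809 (SD, n = 36) per mouse below, a difference of 0.0589 (two-sided permutation test, p = 0.800).

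The series asks which transcripts of the tumours go with survival. Among genes higher in the mice below the median, Cyp2c69 (ENSMUSG00000092008), a cytochrome P450 of the liver, differed by 6.03 ± 0.69 (log2 fold change ± SE, 36 mice below minus 83 above, adjusted p = 2.68e-10). Cyp7a1 (ENSMUSG00000028240), the rate-limiting enzyme of bile acid synthesis, differed by 5.39 ± 0.64, the liver-secreted protein Fgl1 (ENSMUSG00000031594) by 4.26 ± 0.55 and the peroxisomal enzyme Hacl1 (ENSMUSG00000021884) by 1.71 ± 0.26. The organic anion transporters Slc22a26 and Slco1a4 differed by 5.56 ± 0.67 and 5.15 ± 0.62, and the uridine phosphorylase Upp2 by 2.56 ± 0.34. The further P450 genes Cyp4a14, Cyp3a41a and Cyp2c37 differed by 5.23 ± 0.66, 4.76 ± 0.64 and 5.15 ± 0.69. The water and glycerol channel Aqp3 differed by 3.22 ± 0.45. Aqp3 turned to -0.27 without strain MEE (edgeR, adjusted p = 0.949) and to -0.0019 in DESeq2 (adjusted p = 0.999). The highest level of each of these genes except Aqp3 was in mouse TAS-I1, and that of Aqp3 in mouse MEE-E2. TAS-I1 held 92.7% of the summed CPM of Cyp2c69 over the 119 mice, at 1269 CPM, against a highest value of 6.34 CPM above the median. The class medians of Cyp2c69 were 0.0485 CPM above and 0.0976 CPM below, both under the 0.269 CPM that 3 counts make in the shallowest mouse. In TAS-I1 the hepatocyte list took 19.3% of all counts, and in LAX-E2, a mouse above the median with Cyp2c69 at 3.87 CPM, it took 24.97%. Y-linked genes stood at 7.64 CPM in TAS-I1 and at 160 CPM in LAX-E2, and what sets the Cyp2c69 levels of these mice apart was not tested.

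**Figure D1:**
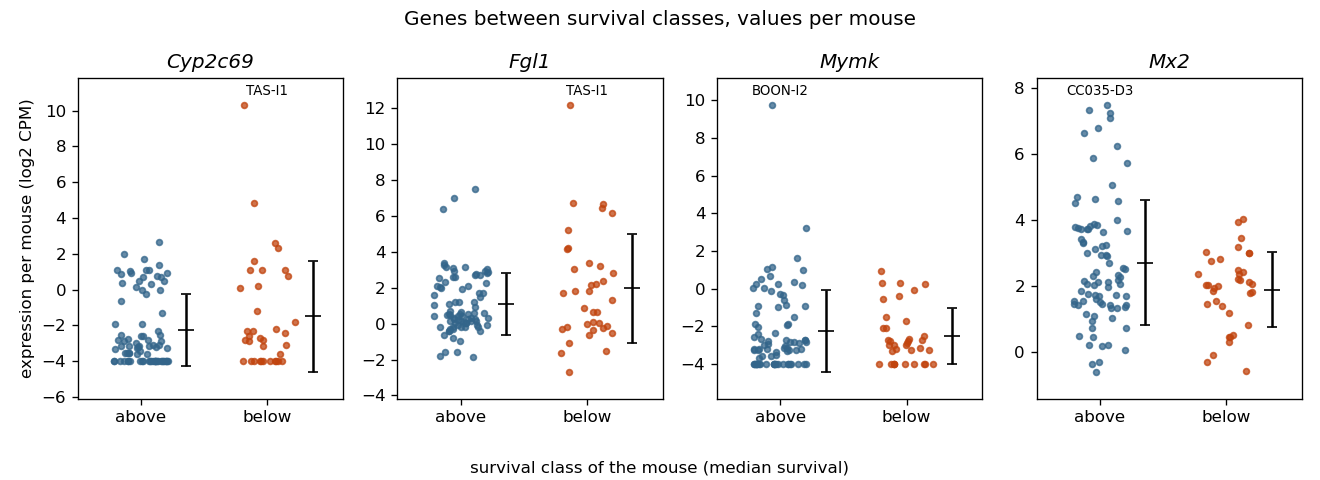
Expression per mouse (log2 CPM) of Cyp2c69, Fgl1, Mymk and Mx2 in mice above (n = 83) and below (n = 36) median survival, with the mean and SD of each class beside the points. The highest point of the first 2 genes is mouse TAS-I1 and that of Mymk is BOON-I2, while the high values of Mx2 are spread over several mice.

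Among genes lower in the mice below the median, the myoblast fusion gene Mymk (ENSMUSG00000009214) differed by -5.30 ± 1.05 (log2 ± SE, adjusted p = 0.000503), the embryonic myosin heavy chain Myh3 by -5.24 ± 1.05 and the atrial myosin light chain Myl4 by -3.13 ± 0.63. Mouse BOON-I2 held 95.02%, 94.1% and 83.1% of the summed CPM of these 3 genes. With strain as a covariate they turned to 0.48, 0.12 and 0.38 (edgeR, adjusted p of 0.826, 0.972 and 0.720). The intestinal genes Defa24, a Paneth cell defensin, Sis, which encodes sucrase-isomaltase, and Clca4b differed by -5.39 ± 1.07, -4.94 ± 1.02 and -4.66 ± 1.04, and were highest in mouse LAX-G3. Clca4b turned to 0.0073 with strain as a covariate (edgeR, adjusted p = 0.997). The kidney genes Kap and Fxyd2 differed by -5.33 ± 1.16 and -2.47 ± 0.55 and were highest in mouse CC081-C5. The immunoglobulin variable genes Ighv1-7 and Igkv4-59 differed by -4.45 ± 0.91 and -3.33 ± 0.71 and were highest in LAX-K2, and Hhip, which binds hedgehog ligands, differed by -4.04 ± 0.86 and was highest in KAV-G2. Mx2 (ENSMUSG00000023341), an interferon-induced antiviral GTPase, differed by -1.95 ± 0.41 (adjusted p = 0.00139), with class medians of 4.75 CPM above and 4.04 CPM below, and its highest mouse, CC035-D3, held 10.5% of the summed CPM. Sequence shared with close paralogs makes the split of counts among the Cyp2c, Cyp3a, defensin and immunoglobulin genes uncertain.

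In all, 267 of 17091 tested genes passed an adjusted p of 0.05 between the classes (edgeR, two-sided), 168 higher and 99 lower in the mice below the median. A single mouse held a median of 47.9% of the summed CPM of the 168 genes and 55.9% of that of the 99 genes, against 3.21% over all tested genes. TAS-I1 was the highest mouse of 61.3% of the 168 genes, and without it 57 higher and 90 lower genes passed. limma-voom passed 0 of the same 17091 genes, with 484 at an unadjusted p under 0.05 against 1544 in edgeR, and DESeq2 passed 285. With strain as a covariate 0 genes passed (edgeR, 1996 at an unadjusted p under 0.05). Without the 23 libraries in which the genes of another tissue took over 1% of counts, 120 genes passed. Cyp2c69, Slc22a26, Cyp4a14, Cyp3a41a and Cyp2c37 then stood at -0.29, -0.69, -0.86, -1.25 and -0.31. None of these passed (edgeR, adjusted p of 0.949, 0.840, 0.777, 0.551 and 0.944), so no lower level below the median is shown for them. Within the 35 libraries with more than 10 CPM of the seminal vesicle gene Svs5, 0 genes passed (edgeR, 765 at an unadjusted p under 0.05), and within the 132 others 262 genes passed (edgeR).

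Of the 34 gene lists, 501 member genes were tested between the classes, and 10 of them passed over all genes tested. Among 17 hepatocyte genes 1 rose below the median, the P450 gene Cyp2e1 (3.26 ± 0.58, log2 ± SE), and 5 were higher adjusted over the list alone. Among 16 pancreatic acinar genes 1 rose, the trypsinogen Try5 (3.16 ± 0.79), and 3 were higher adjusted over the list alone. The gluconeogenic enzyme Pck1 rose (2.21 ± 0.57) among 11 adipocyte genes, and was the 1 gene of that list adjusted over the list alone. Of 6 kidney and adrenal genes 3 fell, the phosphate transporter Slc34a1 (-4.72 ± 0.99), uromodulin, Umod (-4.998 ± 1.17), and Kap, and 5 were lower adjusted over the list alone. The antimicrobial lectin Reg3g fell (-3.32 ± 0.87) among 9 intestinal genes, of which 4 were lower and 1 higher adjusted over the list alone. Pate4 fell (-4.65 ± 1.12) among 7 reproductive tract genes, of which 4 were lower adjusted over the list alone. Mouse CC081-C5 held the highest share of kidney genes of any library (0.465% of counts), LAX-G3 that of intestinal genes (0.755%) and LOX-B4 tumour 3 that of reproductive tract genes (23.9%). Umod also stood at 3.49 to 15.7 CPM in 33 further libraries. All mice of CC001, CC036, CC058 and CC081, where every mouse held Umod, were above the median. Of the other strains with Umod in every mouse, CC021 held 2 mice above and 1 below. GIT held 2 and 2, LAX 4 and 2, and Piping 1 and 2. The falls of the kidney genes thus do not part survival class from this set of libraries.

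Among lists of the tumour and its stroma, Mx2 was the 1 of 19 genes of the type I interferon list that fell, and the eosinophil chemokine Ccl11 (-1.68 ± 0.43, log2 ± SE, adjusted p = 0.0148) the 1 of 19 inflammatory cytokine genes. Both were also the 1 gene of their list adjusted over the list alone. Adjusted over the list alone, Itln1 (-2.63 ± 0.83) passed among 20 mesothelial genes, Myh11 (-1.67 ± 0.52) and Lmod1 (-1.31 ± 0.44) among 10 smooth muscle genes, and the p53 antagonist Mdm2 (-0.41 ± 0.12) among 16 p53 targets, and none of these 4 passed over all genes (adjusted p of 0.0879, 0.0807, 0.146 and 0.0534). In 23 further lists 0 members passed either way in edgeR. These were the lists of mesenchymal markers (18 genes), cell cycle (30), matrix and fibroblasts (20), endothelium (14), hypoxia and glycolysis (18), oxidative phosphorylation (19), interferon gamma and antigen presentation (20), T cells (23), B and plasma cells (14), macrophages (20), neutrophils (11) and complement (15). They were also those of Hippo targets (14), mesothelioma tumour suppressors (13), the unfolded protein response (16), immediate early genes (12), cholesterol synthesis (17), ribosomal proteins (20), skeletal muscle (15), erythroid cells (7), mast cells (8), nerve and glia (9) and sex-linked genes (4). Among the members of all lists, limma-voom gave an unadjusted p under 0.05 to 1 gene each of the type I interferon, complement, p53 and sex-linked lists.

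A score per mouse, the mean centred log2 CPM over the members of a list, differed between the classes for 0 of 34 lists (two-sided permutation test, lowest adjusted p = 0.869, 1 list at an unadjusted p under 0.05). That list was the Y-linked genes, with a score of 0.31 ± 2.18 (SD, n = 83) above and -0.71 ± 2.46 (SD, n = 36) below (unadjusted p = 0.0256). The cell cycle score differed by 0.06 (95% interval -0.31 to 0.43), the T cell score by -0.30 (-0.94 to 0.34), the matrix score by 0.15 (-0.34 to 0.65) and the hepatocyte score by 0.46 (-0.63 to 1.55). camera with an estimated correlation passed 0 of 34 lists, with a lowest adjusted p of 0.966.

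The same contrast was then made between mice of one strain, in the 13 strains with both classes (35 mice above and 22 below). Among genes past the filters on level, symbol and fold change, those of lowest p were all higher below the median. They were the zinc finger gene Rbak (0.75 ± 0.17, log2 ± SE), the monooxygenase gene Moxd1 (2.46 ± 0.60), Lrrc17 (1.86 ± 0.48), the circadian repressor Per2 (0.85 ± 0.22) and the T-type calcium channel Cacna1g (1.75 ± 0.47). None passed in edgeR, at an adjusted p of 0.366 each, and Rbak, Lrrc17, Per2 and Cacna1g passed in DESeq2 (adjusted p of 0.0198, 0.0198, 0.0414 and 0.0249). edgeR passed 0 of 16481 genes (1882 at an unadjusted p under 0.05), limma-voom passed 0 (1393 at an unadjusted p under 0.05), and DESeq2 passed 65, of which 50 were higher and 15 lower below the median. The lowest p in DESeq2 was that of the fibrillin gene Fbn2, at 2.26 (adjusted p = 0.0198), for which edgeR gave 2.26 with an adjusted p of 0.366.

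Within strain 0 of 34 list scores passed the adjusted threshold. The score of interferon gamma and antigen presentation genes differed by -0.90 (two-sided permutation test within strain, p = 0.00475, adjusted p = 0.161 over 34 lists). The B and plasma cell score differed by -1.05 (p = 0.0324), the T cell score by -0.92 (p = 0.0400) and the p53 target score by -0.20 (p = 0.0380), while the endothelium score differed by 0.61 (p = 0.0173), each with an adjusted p of 0.272. The matrix and fibroblast score differed by 0.60 (p = 0.0600, adjusted p = 0.303), the macrophage score by -0.23 (p = 0.245), the neutrophil score by 0.07 (p = 0.796) and the cell cycle score by 0.01 (p = 0.970).

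Whether the contrast differed between strains was tested in the 7 strains with at least 2 mice in each class (22 mice above and 15 below). The genes of lowest p were the olfactory receptor Olfr1217 (F = 8.74, adjusted p = 0.170), Asb1, the homeobox gene Msx1, the transcription factor Tfcp2l1 and the MEF2 coactivator Mamstr (adjusted p = 0.202 for the last 4). edgeR passed 0 of 16454 genes (1393 at an unadjusted p under 0.05) and limma-voom passed 0 (654 at an unadjusted p under 0.05). Without the libraries with over 1% of another tissue 2 genes passed, Rpl17-ps9 and Gm6136 (adjusted p = 0.00152 each), which are named because they were the only calls and were chosen after their values were seen. In simulated data the interaction test recovered 2 of 100 genes that differed by 2 on the log2 scale. That difference was placed in the mice below the median of a single strain, so other patterns were not covered.

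The strains differed widely. Cwc22 (ENSMUSG00000027014), a splicing factor gene in a segment whose copy number varies among mouse strains, stood at 9.23 ± 0.21 (log2 CPM, SD, n = 3) in CC058, 8.84 ± 0.63 (n = 6) in TAS and 8.09 ± 0.60 (n = 7) in LOX. In the other strains its mean lay between 4.89 ± 0.25 (n = 4) in VUX and 5.59 ± 0.12 (n = 3) in CC036, and 93.3% of its variance lay between strains. The ribosomal protein pseudogene Rps2-ps13 ranged from 1.81 ± 1.37 (n = 4) in Rogan to 9.01 ± 0.32 (n = 7) in LOX, the ferritin pseudogene Ftl2-ps from -3.63 ± 0.38 (n = 3) in CC035 to 7.81 ± 0.31 (n = 4) in YID, and Rps15a-ps7 and Rpsa-ps2 were both highest in CC021, at 7.01 ± 0.33 and 7.24 ± 0.11 (n = 3). The unnamed genes AC133509.1 and AC122453.1 had 90.02% and 88.5% of their variance between strains. Umod, Myl4 and Clec2h were also among the genes of lowest p, each with its highest strain mean resting on 1 mouse, CC081-C5, BOON-I2 and LAX-G3, and Myl4 did not pass in limma-voom (adjusted p = 0.468). Umod also stood between 2.11 and 13.3 CPM in every mouse of CC001, CC021, CC036, CC058, GIT, LAX and Piping, and at 2.49 CPM or less in the mice of the strains other than these and CC081. Sequence shared with the parent genes leaves the levels of the 4 pseudogenes uncertain. Over the mice of the 25 strains with at least 3 mice, edgeR passed 14283 of 20687 genes, limma-voom 10385, and both 9394.

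Genes of the B cell, T cell and interferon gamma lists differed between strains in both tools. Of 14 B and plasma cell genes 12 passed in edgeR and 12 in limma-voom. Ms4a1, which encodes the B cell antigen CD20, stood at 7.80 ± 2.18 (log2 CPM, SD, n = 6) in CC053 and at -0.20 ± 1.58 (n = 4) in CC040. Of 23 T and cytotoxic cell genes 21 passed in edgeR and 17 in limma-voom, with Foxp3, the regulator of regulatory T cells, at 3.92 ± 2.44 (n = 7) in CC044 and -1.02 ± 0.44 (n = 3) in CC021. Of 20 interferon gamma and antigen presentation genes 18 and 14 passed, with the T cell chemokine Cxcl9 at 6.91 ± 2.60 (n = 7) in CC044 and 0.09 ± 1.79 (n = 4) in CC040. Other immune lists went less evenly, and of 14 neutrophil genes 12 passed in edgeR and 2 in limma-voom. Of 8 mast cell genes 6 and 1 passed, of 20 cytokine genes 17 and 2, and of 20 macrophage genes 12 and 11. The B and plasma cell score was 3.20 ± 1.69 (n = 6) in CC053 and -2.09 ± 1.53 (n = 4) in CC040, the T cell score 2.53 ± 2.03 (n = 7) in CC044 and -1.55 ± 0.48 (n = 3) in CC021, and 49.7% and 43.03% of their variance lay between strains, against a mean of 23.5% over permuted labels (permutation test, adjusted p = 0.000765 and 0.0105 over 34 lists). The labels name whole tumours, and whether a sample also held lymphoid tissue cannot be read from them.

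Proliferation and matrix genes differed as well. All 30 cell cycle genes passed in edgeR and 29 in limma-voom, with the replication gene Mcm2 at 7.47 ± 0.65 (log2 CPM, SD, n = 7) in CC044 and 4.98 ± 0.16 (n = 3) in Piping, and the mitotic gene Ube2c at 6.68 ± 0.52 (n = 4) in CC040 and 3.90 ± 0.31 (n = 3) in KAV. Of 20 matrix and fibroblast genes 6 passed in edgeR and 16 in limma-voom, with the collagen gene Col1a1 at 13.96 ± 1.05 (n = 3) in CC046 and 9.89 ± 0.97 (n = 6) in CC053, and lumican, Lum, at 9.79 ± 0.82 (n = 3) in CC060 and 4.995 ± 0.84 (n = 6) in CC053. Over all 20687 genes 14283 passed in edgeR and 10385 in limma-voom. Matrix genes thus passed less often than genes in general in edgeR and more often in limma-voom. The cell cycle score was 0.97 ± 0.33 (n = 7) in CC044 and -0.94 ± 0.26 (n = 3) in KAV (44.9% of variance between strains, permutation test, adjusted p = 0.00605). The matrix score was 1.31 ± 0.50 (n = 4) in Rogan and -1.71 ± 0.76 (n = 6) in CC053 (44.4%, adjusted p = 0.00753, permutation test). In the 132 libraries without seminal vesicle transcripts 10 of the 15 lists past the threshold passed, the cell cycle list was no longer among them (42.2% of variance, adjusted p = 0.0573, 84 mice), and the matrix, T cell and B cell lists were. In the libraries with Umod at or below 2 CPM 6 lists passed (75 mice of 17 strains), the cell cycle, matrix, T cell and B cell lists among them, and in those with Umod above 2 CPM 0 lists passed (28 mice of 8 strains), with 36.6%, 47.5%, 38.2% and 38.7% of the variance of these 4 lists between strains. These tests of scores between strains were chosen after the data had been seen.

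**Figure D2:**
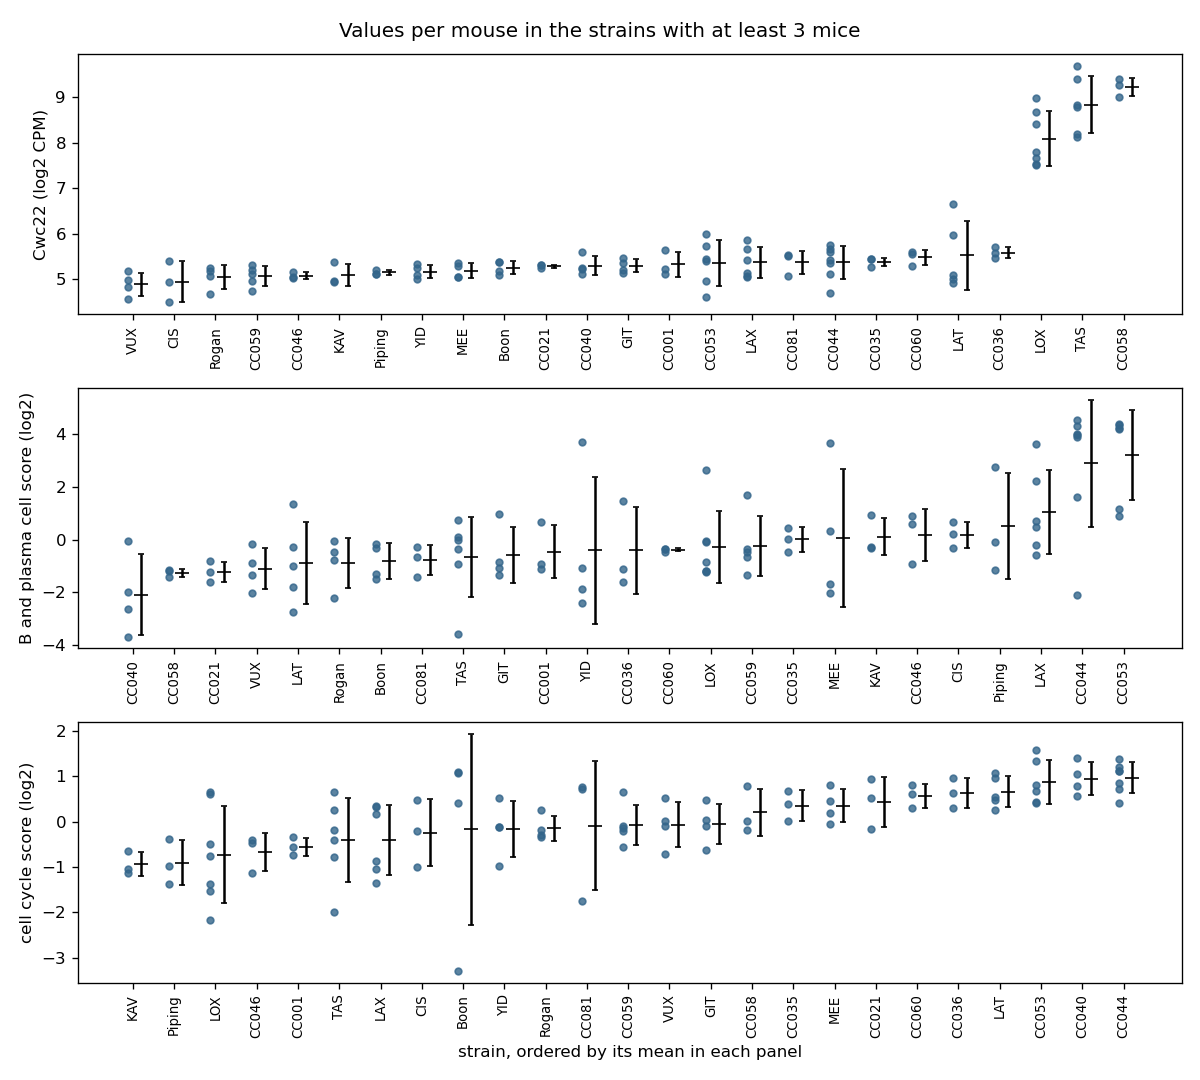
Cwc22 expression (log2 CPM), B and plasma cell score (log2) and cell cycle score (log2) per mouse in the 25 strains with at least 3 mice, strains ordered by their mean in each panel, with mean and SD beside the points. CC058, TAS and LOX stand apart for Cwc22, and CC053 and CC044 have the highest B and plasma cell means.

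Some tumour libraries held much RNA of other tissues. The hepatocyte list took 24.97% of counts in LAX-E2 (Wilson 95% interval 24.95 to 24.99) and 19.3% in TAS-I1 (19.24 to 19.27), where albumin, Alb, reached 159738 and 100918 CPM. The reproductive tract list took 23.9% in LOX-B4 tumour 3, the pancreatic acinar list 7.56% in MEE-A3 tumour 2 and 4.48% in TAS-H2, and the skeletal muscle list 6.96% in TOFU-K2, 6.26% in GIT-K1 tumour 2 and 6.06% in CC046-L3 tumour 1. In all, 23 libraries of 22 mice held over 1% of a list of another tissue, 12 above and 11 below the median. The median shares over the 167 libraries were 0.0404% for hepatocyte, 0.00191% for acinar and 0.0122% for skeletal muscle genes.

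Tumours of one mouse resembled each other more than tumours of different mice of the same strain. The mean correlation of log2 CPM across genes was 0.946 over 67 pairs of tumours of one mouse and 0.883 over 332 pairs of different mice of one strain, a difference of 0.0621 over 122 tumours of 19 strains. Permuting the mouse labels within strain gave p = 1e-05, the smallest these permutations can give (one-sided). Within the libraries without seminal vesicle transcripts the difference was 0.0681. Tumours of one mouse often carry adjacent library numbers, as in CC044-J3 and CC053-F1. The test therefore does not part the mouse from libraries that were handled together. The closest pair of the series, FUF-H2 tumours 1 and 2, still differed by more than sampling noise (chi-square of 2.98 per degree of freedom), and no pair was counted as 1 sample. The next lowest value among the 20 closest pairs was 17.97, and whether the FUF-H2 libraries come from 1 tumour was not tested.

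The strain label of a library was compared with its expression over 300 genes that mark strains, with the library's own mouse left out. Of 144 libraries with other mice of their strain to compare with, 134 correlated best with their labelled strain and 10 with another, 5 of these by more than 0.1. Of the other 5, CC044-F2, CC053-A1 tumour 1 and both tumours of CC044-D3 were nearer to another strain by 0.00927 to 0.0606. Once the 5 libraries over 0.1 were left out of the strain means, 6 libraries passed that margin. CC044-F2 was then nearer to CC059 (r = 0.771) than to CC044 (0.661), by 0.110, and CC053-A1 tumour 1 nearer to CC035 by 0.0736. CC044-F2 was still not set apart, since that choice rests on the first comparison. The library labelled MEE-A3 tumour 1 had r = 0.963 with CC044 and 0.424 with MEE. The library labelled ROGAN-C3 tumour 2 had 0.944 with CC046 and 0.622 with Rogan, LOX-D1 tumour 2 had 0.949 with LAT and 0.654 with LOX, LAT-D3 tumour 2 had 0.912 with LOX and 0.742 with LAT, and LAT-F5 tumour 2 had 0.950 with CC059 and 0.805 with LAT. CC059-F2 tumour 2 had 0.896 with LAT and 0.889 with CC059, and was set apart with these 5 because over all genes its closest library was LAT-F5 tumour 1 (r = 0.980). Without these 6 libraries 248 genes passed between the survival classes and 14468 between strains.

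**Figure D3:**
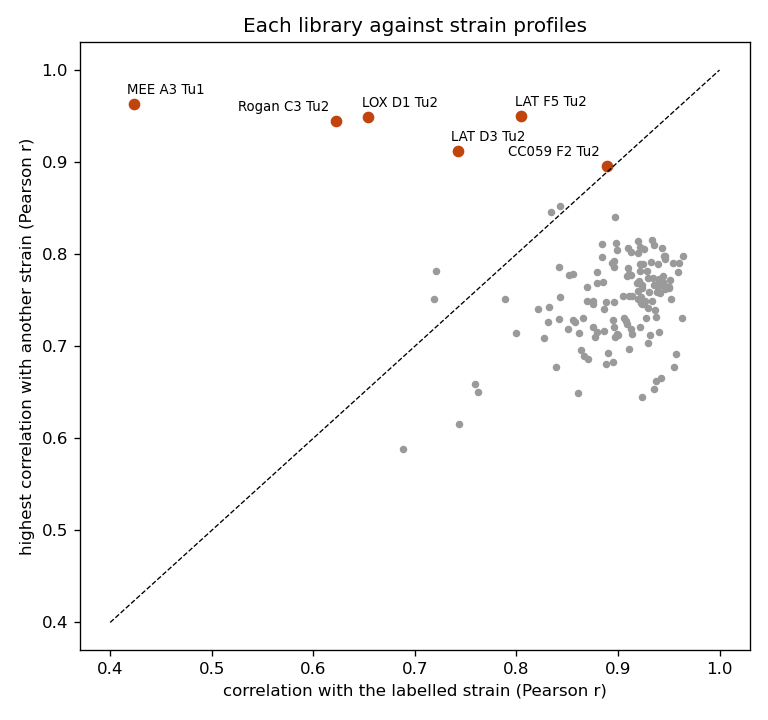
Correlation (Pearson r) of each library with its labelled strain on the horizontal axis and the highest correlation with another strain on the vertical axis, 144 libraries, with the line of equality dashed. The 6 named libraries in red lie above the line.

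Transcripts of the seminal vesicle were found in a sharply separate set of libraries. Svs5, a seminal vesicle secretory protein, stood at 142563 CPM in LOX-B4 tumour 3, between 101.7 and 258 CPM in 34 further libraries, and at 0.0848 CPM or less in the other 132. The lung surfactant gene Sftpc, highest in LOX-F4 (32275 CPM) and CC059-E2 tumour 2 (16817 CPM), stood between 34.2 and 86.3 CPM in the rest of the same 35 libraries. Outside them it stood at 0.530 CPM or less except in MEE-I2, at 87.6 CPM. The set held 24 libraries above and 11 below the median, from 29 mice. Y-linked genes were under 10 CPM in 17 of the 35 libraries. The kidney gene Umod stood at 2554 CPM in CC081-C5, between 3.49 and 15.7 CPM in 33 further libraries, and at 1.47 CPM or less in the other 133, a set that shares 0 libraries with the first. It covers 30 mice of 10 strains, and all libraries of 7 strains.

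**Figure D4:**
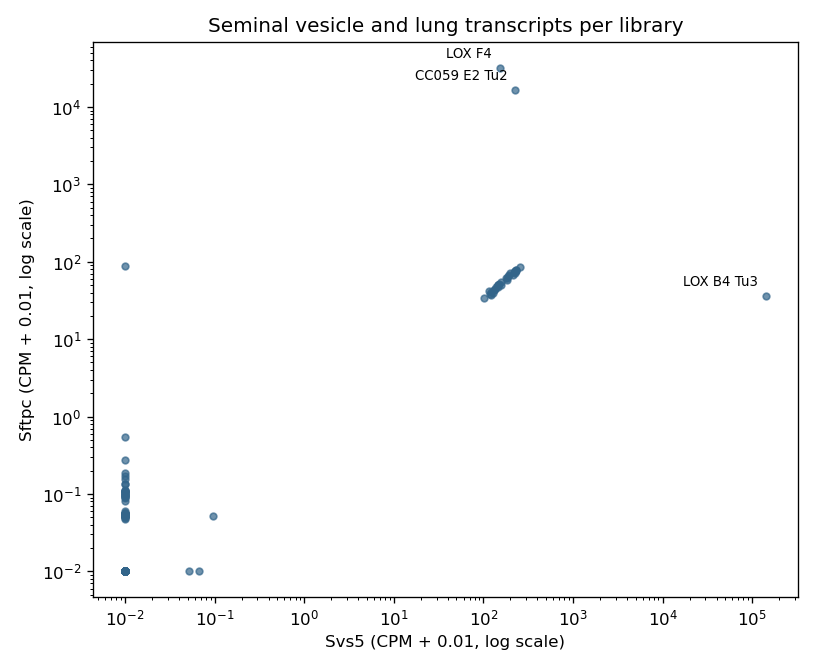
Svs5 against Sftpc in each of the 167 libraries (CPM + 0.01, both axes on a log scale), with the highest libraries named. The 35 libraries with Svs5 form a cluster apart from the rest, and they hold Sftpc as well.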

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

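The splits of the mice, the tests on the 6 libraries nearer to another strain and the tests of Y-linked against seminal vesicle transcripts and of kidney transcripts were chosen only after the result was seen, as were the divisions of libraries by Svs5 and by Umod.

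Between the survival classes 267 genes passed, and in 75 of the 168 higher and 60 of the 99 lower genes a single mouse held over 50% of the summed CPM, against 286 of all 17091 genes. Of 100 splits of the 119 mice into groups of 83 and 36, the real one included, 95 gave as many genes, with a highest other count of 1768, so chance is not excluded. The median of the other splits was 533 genes in edgeR, above the real 267, and 0 in limma-voom, where the highest was 325. These counts were thus mainly those of edgeR, and whether they point to a structure of the samples was not tested. Without the libraries in which another tissue took over 1% of counts 120 genes passed, so RNA of other tissue in a few tumours may account for much of the count, and without mouse TAS-I1 57 higher and 90 lower genes passed, against 168 and 99. A difference in the tumours that goes with survival stays open, though 0 genes passed in edgeR within strain or with strain as a covariate, and 0 in limma-voom with strain as a random block, where DESeq2 passed 65 within strain.

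The expression of strain-marking genes was nearer to another strain in 10 libraries, of which 6 were set apart, 5 by a margin over 0.1 and CC059-F2 tumour 2 (margin 0.00693) by its closest library. Of the 5, 2 had a partner out of place the other way by over 0.1 (LOX-D1 tumour 2 and LAT-D3 tumour 2, library numbers 56 and 58), and LAT-F5 tumour 2 and CC059-F2 tumour 2 (numbers 9 and 11) are each nearest to the other's mouse, though the latter matched its own strain best once the 5 were left out of the strain means, so a mislabelled or exchanged library stays a candidate explanation that these counts do not settle. Y-linked genes stood at 4.70 CPM in LOX-D1 tumour 2 and 28.9 in LAT-D3 tumour 2, against 27.96 CPM in the rest of LOX-D1 and 6.55 to 8.44 in the rest of LAT-D3, at 3.17 in ROGAN-C3 tumour 2 (other tumour 175, nearest mouse CC046-J5 3.77) and 6.26 in MEE-A3 tumour 1 (other tumour 43.2, nearest mouse CC044-K1 5.52 to 11.7). They stood at 65.6 CPM in LAT-F5 tumour 2 (other tumour 19.9) and 44.9 CPM in CC059-F2 tumour 2 (other tumour 69.8), while the median ratio of highest to lowest within a mouse was 1.70. Other tissue in the library is argued against, since 0 of the 6 libraries held over 1% of another tissue's list, and no biological explanation was tested. With the 5 left out of the strain means, CC044-F2, which is not among the 6, was nearer to CC059 than to CC044 by 0.110.

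Seminal vesicle transcripts appeared in 35 libraries, and kidney transcripts in 34 others. The 9 genes that reach at least 1000 CPM in LOX-B4 tumour 3 and not outside the set stood in the other 34 libraries at a median of 0.121% of its level (quartiles 0.117% to 0.123%, a ratio of 1.05), and the lung gene Sftpc of 2 of these libraries appeared in the same set. The 6 genes above 200 CPM in CC081-C5 with a median under 0.1 CPM outside the kidney set stood in its other 33 libraries at a median of 0.232% of that level (0.187% to 0.508%, quartiles 0.192% to 0.278%, a ratio of 1.44, near the limit of 1.5), though 4 of the 6 reach high levels in some library outside the set (Sult1d1 150, Kap 105.3, Keg1 47.3 and Pkhd1 18.4 CPM), and the gene limits were set after an earlier choice left 2 genes. Of the library numbers, which repeat over the series but not within either set, 34 of 35 in the first set lie in 1 to 36 and all 32 known in the second in 37 to 71, and both patterns are consistent with carry-over between libraries that were pooled or handled together, though which step is not given in the sources used here. Y-linked transcripts stood under 10 CPM in 17 of the 35 libraries. The sex of the mice is not given, and Y-linked levels ran from 2.24 to 975.3 CPM over all libraries. A level under 10 CPM therefore does not decide on seminal vesicle tissue in each tumour, and no biological explanation was tested.

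The counts of the other comparisons were set against splits as well. Within strain, where 0 genes passed (edgeR, 1882 at an unadjusted p under 0.05), the comparison with splits decides nothing, since all 60 of 60 splits reach a count of 0, and the highest other count was 4. For the interaction, where 0 genes passed (edgeR, 1393 at an unadjusted p under 0.05), it decides nothing for the same reason (60 of 60). The highest other count was 85 in edgeR and 34 in limma-voom, and the cause of such counts was not tested. Between strains 14283 genes passed, and the real labels were the 1 of 25 sets of labels that gave as many, so chance is excluded, which for strains held whole by a set of libraries does not part strain from library set. The highest other count was 5940 in edgeR and 28 in limma-voom, where the real labels gave 10385, so a call by edgeR alone between strains carries less weight than 1 by both tools. Without the libraries with over 1% of another tissue 13483 genes passed between strains. Since the set of libraries with kidney transcripts holds 7 strains whole, the strains of that set were compared among themselves (28 mice of 8 strains), and 2481 genes passed in edgeR and 503 in limma-voom.

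A gap between 1 mouse and the rest of its strain was tested in 135 groups of named gene and strain, with 18 gaps past Dixon's 95% limit. Chance passes about 1 in 20 only for independent, normally distributed values. Here the same mice recur over the genes and several strains stand at 0 CPM, so the 18 gaps cannot be set against that rate. The value given is the gap over the whole range of the strain in log2 CPM. Umod stood in 1 mouse and at 0 CPM in the others of its strain in CC040-E4 (0.0632 CPM), CC059-B1 (0.336), LAT-D3 (0.0105), MEE-A3 (0.0231) and TAS-H2 (0.0933), each with a value of 1, which any level gives where the others are at 0, and 4 of these 5 levels lie under the floor of 0.269 CPM. In LOX-D1 it stood at 0.353 CPM against up to 0.0255 (value 0.820). Ftl2-ps stood at 0.410 CPM in TAS-E3 and at 0 in the other TAS mice (value 1), at 0 CPM in CC053-A1 against 1.72 to 6.77 (0.713), and at 0 CPM in MEE-I2 against 0.393 to 0.485 (0.915). Rps2-ps13 was low in BOON-I2 (0.904 CPM against 13.9 to 15.997, value 0.951), in MEE-I2 (0.993 against 9.20 to 14.3, value 0.831) and in TAS-H5 (163 against 535 to 670, value 0.842). AC122453.1 was high in CC053-G3 (1.33 CPM against 0.123 to 0.323, value 0.639) and in LOX-D1 (7.97 against 0.496 to 1.55, value 0.604). Rpsa-ps2 was high in CC053-G3 (3.44 CPM against 0.448 to 0.912, value 0.665) and in CC059-F2 (19.2 against 1.36 to 2.17, value 0.827). Myl4 was high in BOON-I2 (1527 CPM against 1.66 to 1.90, value 0.981) and Clec2h in LAX-G3 (417 CPM against 1.17 to 8.43, value 0.668). LOX-D1, LAT-D3, MEE-A3 and CC059-F2 each hold 1 of the 6 libraries nearer to another strain.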

How the results depend on the processing

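limma-voom with robust variance, the subsets by other tissue, by strain match, by Svs5 and by Umod, and the removal of single mice were chosen only after the result was seen. The other alternatives were planned.

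The count of genes between survival classes (267, with 168 higher below the median) depended on several choices, and where no reason is given the cause was not tested. Without a filter on low counts 1108 genes passed (522 higher, 586 lower, of 32303 tested), and with each tumour as its own sample 479. With Y-linked genes as a covariate 402 passed (349 higher, 53 lower), and with the scores of 4 other-tissue lists as covariates 26. Without libraries with over 1% of another tissue 120 passed (59 higher, 61 lower), of which 88 were among the 267. In only the libraries with Umod at or below 2 CPM 511 passed (439 higher, 72 lower). Without mouse TAS-I1 57 higher and 90 lower genes passed, against 168 and 99. The count was 0 with limma-voom on mice (484 genes at an unadjusted p under 0.05), limma-voom on tumours with mouse as a random block (383), limma-voom with strain as a random block (534), edgeR with strain as a fixed covariate (1996), limma-trend on the second table (697), and edgeR in only the libraries with Svs5 above 10 CPM (765). Leaving out each strain in turn gave between 55 (without TAS) and 485 (without LAX) genes higher below the median, and between 52 (without TAS) and 205 (without CC044) genes lower. DESeq2 passed 285 genes, 140 of them lower, of which 92 were among the 267. Between 208 and 319 genes passed with other scaling, 1 tumour per mouse, a depth covariate, and without late library numbers, doubtful libraries, libraries with Svs5 or 1 of 4 further mice. Within strain DESeq2 passed 65 genes, and every other alternative 0, as did each left-out strain (0 to 0). The interaction passed 2 genes without libraries with over 1% of another tissue and 0 otherwise. Between strains 2481 genes passed in only the libraries with Umod above 2 CPM and 503 with limma-voom there, where 28 mice of 8 strains remain, and between 10385 and 18619 in all other alternatives run.

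Several named genes of the survival contrast changed sign. No value of changed sign passed the threshold, the lowest adjusted p being 0.551, for Cyp3a41a without libraries of other tissue (edgeR). Without libraries of other tissue Cyp2c69 stood at -0.29 (log2), Slc22a26 at -0.69, Cyp4a14 at -0.86, Cyp3a41a at -1.25 and Cyp2c37 at -0.31. With other-tissue scores as covariates Slc22a26 stood at -0.45, Slco1a4 at -0.13, Cyp4a14 at -0.14, Cyp3a41a at -0.14 and Cyp2c37 at -0.11. In DESeq2 Cyp4a14 stood at -0.34 and Aqp3 at -0.0019, and Aqp3 lay between -0.27 (without MEE) and 3.46 (without CC081) with 1 strain left out. In only the libraries with Svs5 above 10 CPM Fgl1 stood at -0.11, Upp2 at -0.36, Hacl1 at -0.14 and Ighv1-7 at 0.18. With strain as a random block Cyp3a41a stood at -0.10, Mymk at 0.031 and Myl4 at 0.13, and with strain as a fixed covariate Mymk at 0.48, Myh3 at 0.12, Myl4 at 0.38 and Clca4b at 0.0073. Myl4 stood at 0.033 with robust limma-voom on mice and at 0.026 with mouse as a random block.

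List scores between survival classes passed in 0 of 34 lists in every alternative run, median scores and camera included. Within strain, Rbak, Lrrc17, Per2 and Cacna1g passed in DESeq2 (adjusted p of 0.0198, 0.0198, 0.0414 and 0.0249). Between strains Myl4 did not pass in limma-voom or in only the libraries with Umod above 2 CPM, and Clec2h not in those at or below it. In limma-voom within the libraries with Umod above 2 CPM, 3 of the 10 named genes did not pass, Clec2h among them. Of the 15 list scores past the threshold between strains, 14 kept their side without other tissue, 14 without doubtful libraries, 10 without Svs5, 6 with Umod at or below 2 CPM and 0 above it, where the kidney list, which holds Umod, is not tested fairly by this division. A covariate of Xist was planned and not run, since the count table has no line for Xist, and only Y-linked genes were used. The labels give no number that pairs a mouse of one class with 1 of the other, and the contrast within strain is the matched comparison run. Genes under 0.269 CPM lie below 3 counts in the shallowest library, and no call on them was read from class medians.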

Other observations

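All tests of list scores between strains given here were chosen after the data had been seen.

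Ribosomal protein and mitochondrial genes also differed between strains. Of 20 ribosomal protein genes 17 passed in edgeR and 16 in limma-voom, with Rps18 at 9.22 ± 0.33 (log2 CPM, SD, n = 4) in CC040 and 6.70 ± 0.27 (n = 3) in KAV. The score was 0.68 ± 0.18 (n = 4) in CC040 and -0.76 ± 0.27 (n = 3) in KAV, with 55.1% of its variance between strains (permutation test, unadjusted p = 1e-05, the smallest these permutations can give, adjusted p = 0.000113). Of 19 oxidative phosphorylation genes 14 passed in edgeR and 11 in limma-voom, with Cox4i1, a subunit of cytochrome c oxidase, at 8.36 ± 0.45 (n = 4) in CC040 and 6.76 ± 0.42 (n = 3) in Piping. Of all 20687 genes 14283 and 10385 passed, shares close to those of the oxidative phosphorylation list. The score of the oxidative phosphorylation list had 38.3% of its variance between strains (permutation test, adjusted p = 0.0303) and did not pass in the libraries with Svs5 at or below 10 CPM (34.9% of variance, adjusted p = 0.175).

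Strain CC040 stood at an end of several lists. It had the highest mean of the mesenchymal score, 0.86 ± 0.18 (SD, n = 4), where LAX had the lowest, -1.01 ± 0.78 (n = 6), with 41.3% of the variance between strains (permutation test, adjusted p = 0.0173), and the list did not pass in the libraries with Svs5 at or below 10 CPM (39.9% of variance, adjusted p = 0.0909) or in those with Umod at or below 2 CPM (38.4%, 0.0767). Its mean of S100a4, a calcium-binding protein of motile mesenchymal cells, was 10.34 ± 0.62 (log2 CPM, n = 4), against 6.32 ± 0.79 (n = 7) in CC044, and that of the receptor tyrosine kinase Axl was 9.61 ± 0.14, against 7.71 ± 1.04 (n = 6) in LAX. The complement score was lowest in CC040, at -1.58 ± 0.27 (n = 4), and highest in CC046, at 1.09 ± 1.26 (n = 3, permutation test, adjusted p = 0.0355), with C1s1 at 3.63 ± 0.87 in CC040. The macrophage score was lowest in CC058, at -1.29 ± 0.34 (n = 3), and highest in Piping, at 0.78 ± 0.74 (n = 3, permutation test, adjusted p = 0.0336). In the libraries with Umod at or below 2 CPM neither the complement list (35.7% of variance, adjusted p = 0.0905) nor the macrophage list (34.9%, 0.099) passed.

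Of 13 mesothelioma tumour suppressor genes 8 passed between strains in edgeR and 7 in limma-voom, where 14283 and 10385 of all 20687 genes passed, and the score of the list did not pass (27.01% of variance, permutation test, adjusted p = 0.331). The deubiquitinase gene Bap1 stood at 6.32 ± 0.37 (log2 CPM, SD, n = 5) in LAT and 5.25 ± 0.78 (n = 3) in CC058 (adjusted p = 6.94e-08 in edgeR and 2.36e-07 in limma-voom). Cdkn2a stood at 6.23 ± 3.56 (n = 3) in CC046 and -0.27 ± 0.43 (n = 3) in CC060, and passed in edgeR (adjusted p = 0.00143) but not in limma-voom (0.519). Of 19 type I interferon genes 12 passed in edgeR and 5 in limma-voom, and the score of the list did not pass (29.6% of variance, permutation test, adjusted p = 0.214). The antiviral genes Mx2 and Mx1 were both highest in CC035, at 6.84 ± 0.82 and 6.31 ± 0.83 (n = 3), against 0.62 ± 0.93 (n = 4) for Mx2 in CC040 and 1.95 ± 0.80 (n = 3) for Mx1 in CC058, and all 3 CC035 mice are above the median.

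The remaining lists past the threshold between strains were the kidney list (76.4% of variance between strains), the intestinal list (58.3%), the hepatocyte list (42.2%), immediate early genes (39.1%), erythroid cells (37.7%) and interferon gamma (43.6%). The kidney mean was highest in CC081 (4.37 ± 4.58, SD, n = 3), where CC081-C5 alone held 0.465% of counts in kidney genes, and the intestinal and hepatocyte means were highest in LAX (3.42 ± 3.18 and 3.39 ± 3.54, n = 6), the strain of LAX-G3 and LAX-E2. The kidney gene Umod was also present at 3.49 to 15.7 CPM in 33 libraries beside CC081-C5. In the libraries with Umod at or below 2 CPM the intestinal list had 26.5% of its variance between strains (adjusted p = 0.338) and the hepatocyte list 36.7% (adjusted p = 0.0902), and neither passed. Immediate early genes did not pass with Svs5 at or below 10 CPM (41.5% of variance, adjusted p = 0.0611) or without other tissue (37.7%, 0.0619), nor erythroid cells with Svs5 at or below 10 CPM (39.2%, 0.0966) or without the libraries nearer to another strain (35.2%, 0.0697). In the libraries with Umod above 2 CPM, where 0 lists passed, the variance between strains was 55.5% for the mesenchymal, 48.4% for the macrophage and 46.4% for the erythroid list. In the libraries with Umod at or below 2 CPM the lists that passed were cell cycle, matrix, interferon gamma, T cells, B and plasma cells and ribosomal proteins. In the libraries without over 1% of another tissue 16 lists passed, 14 of them among the 15, and without the 6 libraries nearer to another strain 14 passed, all among the 15.

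The level of albumin transcripts differed between sets of libraries. The median of Alb was 0.707 CPM in the 17 libraries of the highest numbers, 43.6 CPM in the 35 libraries with Svs5 above 10 CPM and 274 CPM in the rest. The rest held no single level, from 9.14 to 159738 CPM, though the libraries of several strains lay close together. In the rest, Alb stood at 13.9 to 20.7 CPM in PEF2 libraries and at 237 to 359 CPM in CC035 libraries. Among strains with Umod in every mouse, Alb stood at 235 to 374 CPM in CC021 libraries and 234 to 410 CPM in CC058 libraries. In CC001 and LAX libraries Alb stood at 359 to 823 CPM and at 275 to 159738 CPM. Whether the hepatocyte list differs by strain or by set of libraries was not tested. Y-linked genes ranged from 2.24 to 975.3 CPM over the libraries with a median of 23.8 CPM, and 49 of the 167 stood under 10 CPM. Among the 35 mice with several tumours the median ratio of the highest to the lowest Y-linked level within a mouse was 1.70. The sex of the mice is not given in the sources used here. Of the 20 closest pairs of libraries 4 were of different mice.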
